A study of Escherichia coli K-12 with 56 samples.

How the data were processed

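RIL-seq joins RNAs that sit together on an RNA-binding protein: the RNAs pulled down with a tagged protein are ligated to each other and sequenced, so that a chimeric fragment carries a piece of each partner. The series holds 56 samples of Escherichia coli MG1655, per the labels. Of these, 22 are RIL-seq libraries in 11 groups of 2, from strains with a FLAG tag on Hfq, a 3XFLAG tag on ProQ, or no tag. Experiment 1 was sampled at OD 1 in rich medium (LB) or minimal medium (M63), and experiment 2 after 150 min in LB, there also with the other chaperone deleted, per the labels. A further 34 samples are total RNA libraries, which were not analysed here. The labels give no significant chimeras for 2 untagged libraries, which were entered with 0 fragments, and the other 20 have a file. The file of 1 further untagged library, from 150 min in LB, holds a header and no fragments.

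Reads were trimmed with cutadapt 1.16, per the submitters' processing notes. The aligner, the genome build, the annotation and the significance threshold are not given in the sources used here. The deposited values are genomic coordinates, 1 line per end of a fragment and no score other than 0, and per the file headers each file lists the chimeric fragments that passed the submitters' significance test in that library. The unit is therefore other than a count column: the number of lines was counted here, and no value was normalised by the authors, per the file headers. A pair or gene with 0 fragments in a library was not listed as significant there, which is not the same as absent.

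Each end was assigned by its coordinates to a gene in a table of 4651 genes of assembly ASM584v2, used for names and neighbours only since the files name no build. The largest end in the files equals the chromosome length of that assembly. The table gives no strand, so a gene's strand was taken from the reads. A strand could be set for 2777 genes. Of the 2309 genes with at least 10 ends, 92 had over 20% on the minor strand. Ends within 100 nt of a gene on its strand counted to that gene, an sRNA took priority over an overlapping coding gene, and other ends went to intergenic windows of 200 nt. The table has 104 genes of the small RNA class. Reads of near-identical genes (tRNA genes, tufA and tufB, omrA and omrB, the sib, sok and rdl copies, insertion sequences) cannot be told apart with certainty, and their values are uncertain. In all, 4270521 fragments were assigned.

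Ends per gene and fragments per pair were compared between groups with limma 3.58.1 (voom, lmFit, eBayes) in R 4.3.3, scaled by each library's total. Genes needed at least 10 ends in at least 2 libraries. The 8 tagged libraries of an experiment shared 1 fit, which leaves 4 residual degrees of freedom. Adjusted p is Benjamini-Hochberg and the threshold 0.05. Named genes follow a fixed rule. For each comparison they are the 10 largest changes in each direction (5 for pairs) among those past the threshold, with no overlap between the groups and a mean of at least 1000 CPM (scaled to the library total) in the higher group. To these come hfq, proQ, rybB, rbsB, rbsZ, raiZ, cspE, members of the sRNA lists and a fixed list of 57 known pairs. The samples, comparisons, named-gene rule, 57 pairs, 15 gene lists and most alternative analyses were fixed before the data were examined. Those on measured calls, on crossed replicate numbers, on log2 of CPM plus 10, and on identical fragments and left-out replicates in the tagged against untagged comparison were added afterwards.

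The deposited ProQ libraries are shallow, and a gene with 0 ends in them is set by the prior count of 0.5 to a higher CPM than the same 0 in a deep Hfq library. Tested on simulated data with the real depths and the compared groups at their common mean, the plain limma calls included false ones. They made up 23.4% of the unchanged genes for Hfq against ProQ in LB at OD 1, 55.6% in M63, 17.9% at 150 min, 1.4% for the medium on Hfq, 81.7% for the medium on ProQ, 2.1% for the proQ deletion on Hfq and 68.0% for the hfq deletion on ProQ. A stricter class of measured calls was therefore defined after the data were seen. A measured call is past the threshold and has at least 10 counts in each library of the higher group. It also has all of those libraries above the other group's, and a mean above the level that 3 counts would give in the other group. Measured calls keep the adjusted p of the plain fit. Where most features pass, that p is hardly stricter than the unadjusted one. On the same simulated data this class gave 7 false calls among 1261 unchanged genes, 6 of 1312, 2 of 1480, 9 of 1219, 4 of 1380, 22 of 1305 and 6 of 1406, in the same order. Of 67 genes changed by a fold of 4 in the LB comparison at OD 1 it recovered 65, and of 67 changed by a fold of 2 it recovered 46. In Hfq against ProQ at 150 min it recovered 30 of 67 genes and 26 of 67 pairs changed by a fold of 2. The simulation gave all features of a comparison 1 common spread (0.014 or 0.016) and had no step that lists fragments as significant. Real replicates can differ more, as for proQ with 13 and 879 ends on Hfq at 150 min. False calls in the real data can therefore be more frequent than these counts. The unchanged genes also include those with too few counts for a measured call, which lowers the apparent share of false calls. For the difference of the Hfq-over-ProQ ratio between media, a measured call needed at least 10 ends in each of the 8 libraries. This was first set at 3 ends, which gave 17 genes (10 higher, 7 lower), and was raised to 10 after that count and the simulation were seen, which leaves 11 (8 higher, 3 lower). In the simulation the version with 10 gave 3 false calls among 1380 unchanged genes, and the plain calls 76.3%. Most of these 1380 could not be called, as they lacked 10 ends in each library. The share of false calls among genes that could be called is therefore higher, and was not determined. The version with 10 recovered 6 of 15 genes changed by a fold of 2, 10 of 14 by a fold of 4 and 6 of 14 by a fold of 8, so it misses many. For pairs, plain calls were false in 27.5% of the unchanged pairs for Hfq against ProQ, 2.2% for the proQ deletion and 92.7% for the hfq deletion, and measured calls in 14 of 3161, 49 of 2595 and 13 of 2939. The report gives no fold against a group in which a gene is not listed, and fitted values of such genes under the alternatives depend on the prior count.

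The 15 gene lists were Hfq-dependent sRNAs, class II sRNAs, RNAs tied to ProQ in earlier work, type I toxin-antitoxin RNAs, housekeeping RNAs, outer membrane proteins, amino acid and peptide transport of the GcvB type, sugar uptake, iron and respiration, flagella and chemotaxis, global and stress regulators, ribosomal proteins, amino acid biosynthesis, tRNA and rRNA genes. Each was tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and its members also with p adjusted over the list alone. The housekeeping and rRNA lists had fewer than 3 tested genes and gave no result. On simulated data camera is weak for the medium on ProQ and the hfq deletion on ProQ. The lists were also tested on log2 of CPM plus 10 over genes with at least 10 counts in 2 libraries of the groups compared, chosen after the data were seen.

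Library-wide measures (fragments, pairs, shares of small RNAs) were compared between Hfq and ProQ over the 12 tagged libraries without deletions by an exact two-sided permutation test within each condition, with 216 relabellings. Shares of pairs carry Wilson intervals at 95%, which cover counting error only, since the reads have no molecular identifiers: identical copies made up between 25.38% and 54.95% of the fragments of a tagged library. Depth ran from 4391 to 861325 fragments in the tagged libraries. A replicate here is a library with its own label, and p measures the spread between these, which may be technical.

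The alternatives were median-of-ratios size factors, no filter, a filter of 50 counts, limma-trend on log2 of CPM plus 10, only the groups compared, a replicate block, leaving out the 5 most abundant features, flanks of 0 or 200 nt, identical fragments counted once, and each library left out. Counts were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib 3.10.9.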

Results

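RIL-seq libraries from Escherichia coli MG1655 were compared to see which RNAs meet on the RNA chaperones Hfq and ProQ, and how the RNAs on one chaperone differ when the other is deleted. The 16 tagged libraries form 8 groups of 2. In experiment 1 these are Hfq and ProQ in rich medium (LB) and in minimal medium (M63), sampled at OD 1. In experiment 2 they are Hfq, ProQ, Hfq without proQ and ProQ without hfq after 150 min in LB. The 6 untagged libraries form 3 groups of 2. Levels are CPM, the chimeric ends of a gene (or fragments of a pair) scaled to the library's total, given as mean ± SD, and log2 differences carry the standard error (SE) of the limma fit; n = 2 libraries per group throughout. The files list only fragments called significant in their library, so a gene given as not listed may still have been present below that limit. A measured difference passed the limma threshold and also met the count criteria for measured calls.

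The deleted genes were looked at first. No hfq end was listed in either ProQ library of the hfq deletion, against 12 and 20 ends in the ProQ libraries with hfq. No proQ end was listed in either Hfq library of the proQ deletion, against 13 and 879 ends in the Hfq libraries with proQ, so the replicates differed widely for this gene. In the Hfq libraries hfq had 3601 and 3737 ends with proQ and 6237 and 7273 without it. In the ProQ libraries proQ had 0 and 5 ends with hfq and 0 and 7 without it. In experiment 1, hfq had 7828 and 4012 ends on Hfq and 46 and 27 on ProQ in LB, and 1120 and 1077 on Hfq and 0 and 0 on ProQ in M63. The gene proQ had 3670 and 1769 ends on Hfq in LB and 1533 and 1490 in M63, and was not listed in any of the 4 ProQ libraries of that experiment. Of the untagged libraries, replicate 2 in M63 listed 13 ends of hfq and 10 of proQ, and the others listed none.

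Hfq libraries held many more chimeric fragments than ProQ libraries. In LB at OD 1 the Hfq libraries held 861325 and 412753 fragments and the ProQ libraries 44304 and 25295. In M63 the numbers were 294059 and 253571 for Hfq and 6190 and 4391 for ProQ, and after 150 min in LB 381766 and 464706 for Hfq and 42773 and 41495 for ProQ. Without proQ the Hfq libraries held 623592 and 779431, and without hfq the ProQ libraries held 15244 and 17849. The untagged libraries held 0 and 899 fragments in LB, 0 and 873 in M63, and 5 and 0 after 150 min. Over the 3 conditions with untagged libraries, tagged libraries held on average 235756 more fragments than untagged ones (exact two-sided permutation test within conditions, 3375 relabellings, p = 0.0406). That p was 0.148 without replicate 1 and 0.222 without replicate 2. Every tagged library held more fragments than any untagged one, with 4391 in the smallest tagged and 899 in the largest untagged library. No relabelling could therefore give a larger difference in that direction.

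**Figure D1:**
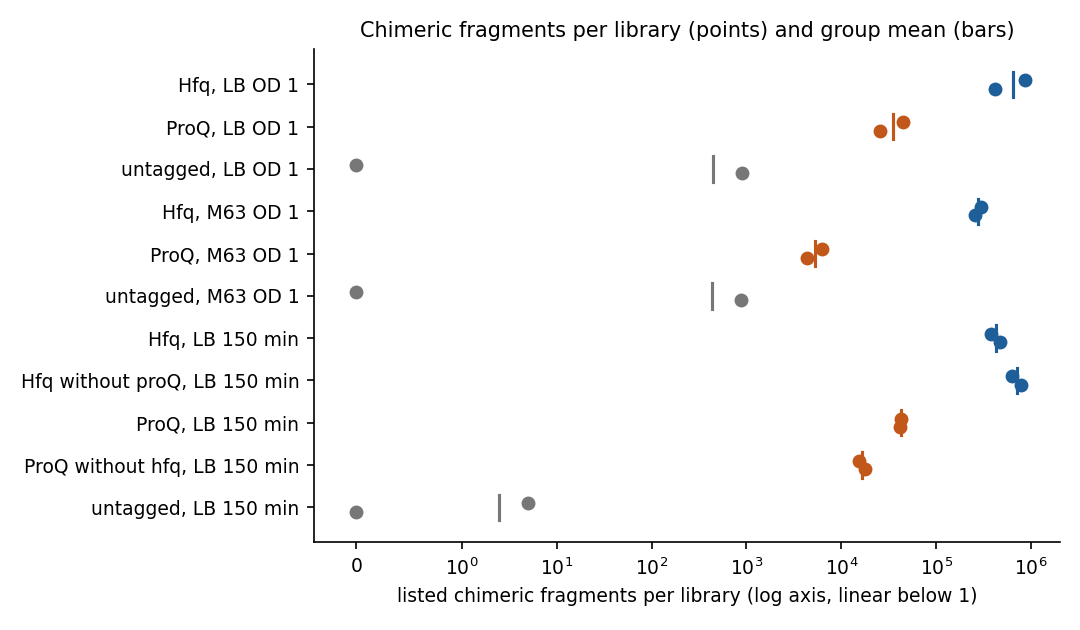
Chimeric fragments per library, with 1 point per library and a bar at each group's mean, on a log axis. The smallest tagged library holds 4391 fragments and the largest untagged one 899.

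Small RNAs sat more often in the second position of a chimera on Hfq than on ProQ, the position where an sRNA bound by its 3' end is commonly ligated. In LB at OD 1 this held for 86.4% ± 0.77 of sRNA ends on Hfq and 64.2% ± 1.87 on ProQ, in M63 for 92.3% ± 0.16 and 69.0% ± 0.75, and at 150 min for 84.0% ± 0.37 and 64.1% ± 0.19 (mean ± SD). Where both partners are sRNAs, an sRNA end always sits in the first position. At 150 min such a pair, rbsZ-rybB, had 146940.3 CPM on ProQ and 450.4 on Hfq, and gcvB-sroC had 13007 and 9478. How much of the difference in position rests on a few such pairs was not tested. Pairs with an sRNA made up 85.05% ± 2.26 of the distinct pairs on Hfq and 62.8% ± 2.55 on ProQ in LB at OD 1, 87.3% ± 0.42 and 62.2% ± 4.87 in M63, and 84.1% ± 0.71 and 56.35% ± 0.10 at 150 min. Averaged over the 3 conditions, Hfq exceeded ProQ by 21.8 points in the second-position share, 25.0 points in the share of pairs with an sRNA, 5.69 points in the sRNA share of ends, 2214 distinct pairs and 417289 fragments. Each of these 5 differences had p = 0.00926 in an exact two-sided permutation test, the smallest p that its relabellings allow. The difference in pairs was smaller with each library thinned to 4391 listed fragments, which does not repeat the significance call: pairs averaged 818 on Hfq and 472 on ProQ in LB at OD 1, 924 and 161 in M63, and 854 and 480.5 at 150 min. Ends in the 100 nt after coding genes made up 2.84% ± 0.10 on Hfq and 14.05% ± 0.59 on ProQ in LB at OD 1, which was not tested.

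**Figure D2:**
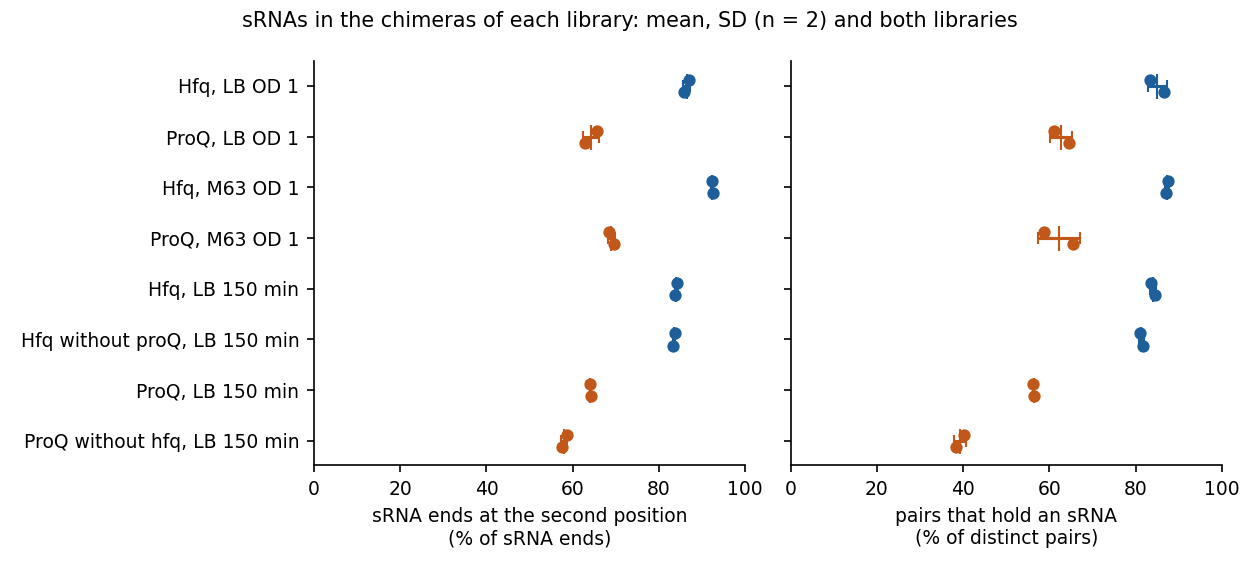
Percent of sRNA ends in the second position of a chimera (left) and of pairs with an sRNA (right), with each library, mean and SD. Hfq libraries in LB at OD 1 average 86.4% and ProQ libraries 64.2%.

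In LB at OD 1, the sRNA RaiZ and the cold shock mRNAs cspE and cspA had far higher levels on ProQ than on Hfq, and rplK and fdoG on Hfq than on ProQ. The sRNA raiZ, made from the 3' end of raiA, reached 113270 ± 16245 CPM on ProQ and 97.2 ± 31.9 on Hfq (log2 difference -10.18, SE 0.38), cspE reached 55170 ± 9601 and 28.3 ± 29.7 (-11.42, SE 0.68), and cspA 33970 ± 9142 and 32.6 ± 2.80 (-10.01, SE 0.44). The prophage gene recE had 15862 ± 3497 CPM on ProQ and 4.40 on Hfq. The sRNA ryjB had 2219 ± 517 and yfcZ 1335 CPM on ProQ, and neither was listed on Hfq. Also lower on Hfq were sibB (-10.22, SE 1.77), the antisense RNA agrA of a type I toxin-antitoxin locus (-9.16, SE 0.93), ymfL (-9.10, SE 2.02) and the sRNA glmY (-9.10, SE 1.21). On Hfq, rplK (ribosomal protein L11) had 10312.5 ± 91.4 CPM, rpsF 2267 ± 5.70, sucA (2-oxoglutarate dehydrogenase) 2191, proQ 2159 and cyoB 1597, and none of these was listed on ProQ. The same held for rpsT, lrhA (2132), thrP (1892) and gatZ (1741). The formate dehydrogenase gene fdoG had 10915 ± 1575 on Hfq and 63.7 ± 90.1 on ProQ (8.12, SE 0.89). In all, 594 of 1468 genes had a measured difference, 460 higher on Hfq and 134 higher on ProQ.

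Of 29 Hfq-dependent sRNAs tested in that comparison, 17 were measured higher on Hfq, 4 higher on ProQ and 7 did not pass (17 and 4 when adjusted over the list alone). The mRNA-repressing sRNAs chiX (60760 CPM on Hfq and 3793 on ProQ; 4.00, SE 0.37) and arcZ (82825 and 7663; 3.43, SE 0.41) were higher on Hfq. So were cyaR (102788 and 51620; 0.99, SE 0.24) and micF (5.31, SE 0.39), a regulator of the porin OmpF. Higher on ProQ were mcaS (9646 on Hfq and 32473 on ProQ; -1.74, SE 0.24) and rybB, a sigma E-dependent sRNA (377 and 66533 ± 33829; -7.32, SE 0.46). The sRNA rbsZ, from the 3' end of rbsB, had 620 on Hfq and 71082 ± 34021 on ProQ (-6.70, SE 0.43). The signs for spf, micA and omrB changed with median-of-ratios size factors, which moved the median of all genes from 1.29 to 2.67. The mcaS difference is not much larger than that shift toward Hfq, so its size depends on the scaling. The list as a whole did not pass limma's camera test (adjusted p = 0.189). Of 5 class II sRNAs, 4 were higher on Hfq and 1 on ProQ (4 and 1 adjusted over the list alone), with camera adjusted p = 0.378.

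All 10 tested RNAs tied to ProQ in earlier work were measured higher on ProQ (10 adjusted over the list alone), among them the nucleoid protein mRNA hupA (-6.35, SE 0.98) and cspC (-6.80, SE 1.11), though raiA (-1.13, SE 0.41) changed sign with median-of-ratios size factors. Camera gave adjusted p = 1.31e-06, and adjusted p = 0.0839 with an estimated correlation. Of 10 type I toxin-antitoxin RNAs, 6 were measured higher on ProQ (6 adjusted over the list alone). Their camera adjusted p = 3.73e-04 became adjusted p = 0.210 with an estimated correlation. Of 37 ribosomal protein genes, 21 were measured higher on Hfq and 2 on ProQ (21 and 2 adjusted over the list alone), for instance rpsJ at 1313 ± 28.0 CPM on Hfq and not listed on ProQ. That list had camera adjusted p = 0.0048, and adjusted p = 0.776 with an estimated correlation. Of 19 transport genes of the GcvB type, 12 were measured higher on Hfq and none on ProQ (12 adjusted over the list alone), with camera adjusted p = 0.189: the serine and threonine transporter gene sstT had 20553 ± 1627 on Hfq and 283 ± 285 on ProQ (6.62, SE 0.65), and argT 16736 ± 2284 and 452 ± 246 (5.29, SE 0.88). Among 19 outer membrane protein genes 6 were higher on Hfq, such as ompA (4.41, SE 0.38), and 2 on ProQ, of which lpp had 59662 ± 6405 on ProQ and 5136 ± 302 on Hfq (-3.54, SE 0.26; 6 and 2 adjusted over the list alone; camera adjusted p = 0.802). Without the added count criteria 929 genes passed limma, 633 higher on Hfq and 296 on ProQ, and with median-of-ratios size factors 864 and 227, since that scaling moved the median of all genes from 1.29 to 2.67. Many of these rest on ProQ libraries with few or no ends.

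In M63 the same ProQ RNAs led. On ProQ raiZ had 180386 ± 12450 CPM, against 227 on Hfq (-9.64, SE 0.40), cspA 121024 ± 21156 against 128 ± 30.1 (-9.88, SE 0.45), cspE 81567 ± 12853 against 182 ± 22.9 (-8.79, SE 0.70), and recE 22118 ± 2313 against 5.20 (-12.85, SE 1.30). The sRNA ryjB had 16064.5 ± 77.4 on ProQ and 9.80 on Hfq (-10.75, SE 0.67). Not listed on Hfq were agrA (4686 ± 229 on ProQ), the biofilm regulator gene bssR (3454), sibD (2317 ± 323), panC (2046) and cspC (1650.1). On Hfq, the galactitol gene gatZ had 12412 ± 249, ypfM 10571 ± 1212, sstT 6867 ± 1206, the sRNA glnZ 4880, the universal stress protein gene uspA 4646 ± 394, gntU 4645, the malic enzyme gene maeA 3722, rplK 3459 ± 524, lysT 3327 and proQ 2822 CPM, and none was listed on ProQ. In total 226 genes had a measured difference, 187 higher on Hfq and 39 on ProQ, and with no flank 130 did, 105 and 25.

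The sRNA Spot 42 (spf), a regulator of sugar metabolism, had 65638 ± 937 CPM on Hfq and 3412 ± 712 on ProQ in M63 (4.26, SE 0.36), and the iron-stress sRNA ryhB 12936 and 973 (3.70, SE 0.45). With arcZ (4.68, SE 0.52), chiX (2.92, SE 0.42) and cyaR (2.22, SE 0.35), they were among 15 of 29 Hfq-dependent sRNAs measured higher on Hfq. Another 3 were higher on ProQ, as mcaS (-2.15, SE 0.30) and rybB (-4.24, SE 0.55) were (17 and 3 adjusted over the list alone). Camera gave that list adjusted p = 1.65e-04, and adjusted p = 0.204 with an estimated correlation. Of the class II sRNAs 3 of 5 were higher on Hfq and 1 on ProQ (3 and 1 adjusted over the list alone). Among 19 transport genes of the GcvB type, 7 were measured higher on Hfq (8 adjusted over the list alone), with camera adjusted p = 1.65e-04 and adjusted p = 0.229 with an estimated correlation; oppA had 3774 ± 215.9 on Hfq and 696 ± 984 on ProQ (3.28, SE 1.04). Of 10 RNAs tied to ProQ, 5 were measured higher on ProQ and 1 on Hfq (5 and 1 adjusted over the list alone), with camera adjusted p = 0.0162 and adjusted p = 0.204 with an estimated correlation. Of 10 toxin-antitoxin RNAs 3 were measured higher on ProQ (3 adjusted over the list alone; camera adjusted p = 0.0026, and adjusted p = 0.204 with an estimated correlation). The plain limma count was 672 genes, 291 higher on Hfq and 381 on ProQ, and 437 and 321 with median-of-ratios size factors, which moved the median of all genes from -0.31 to 0.40. The ProQ libraries here hold few fragments, and a fit of only the groups compared gave 396 genes. Limma-trend gave 899, 847 higher on Hfq and 52 on ProQ, so the split of the plain calls depends on the method.

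After 150 min in LB, RaiZ, rbsZ and rybB were the most abundant RNAs on ProQ. The sRNA rbsZ had 78083 ± 13080 CPM on ProQ and 459 ± 68.4 on Hfq (-7.42, SE 0.30), and raiZ 96308 ± 5012 and 675 (-7.16, SE 0.25). Similarly, rybB had 76469 ± 14403 and 980 (-6.29, SE 0.28), cspE 54004 ± 13587 and 156 ± 37.5 (-8.44, SE 0.39), ryfD 25170 ± 4488 and 68.9 (-8.58, SE 0.36), cspA 20205 ± 2494 and 51.5 ± 20.6 (-8.66, SE 0.41), and recE 18851 ± 109 and 18.3 (-10.19, SE 0.49). The maltose operon gene malM had 40268 ± 9765 on ProQ and 372 ± 45.7 on Hfq (-6.73, SE 0.33). The glycolytic gene fbaA (1405 CPM) and agrA (1243 ± 24.3) were listed on ProQ and not on Hfq, and cysE (-10.48, SE 1.27), ymfL (-10.06, SE 1.06) and ryjB (-7.45, SE 0.69) were higher on ProQ. Listed on Hfq and not on ProQ were sstT (13504 ± 4427), the gluconeogenic gene pck (6669 ± 871), fdoG (5997), the periplasmic nitrate reductase gene napF (3165), yqeC (1828), hypE (1701), the flagellar regulator gene fliZ (1480.3), thrP (1479.7), yebZ (1476) and yecH (1164). Of 1568 genes, 550 had a measured difference, 429 higher on Hfq and 121 on ProQ.

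**Figure D3:**
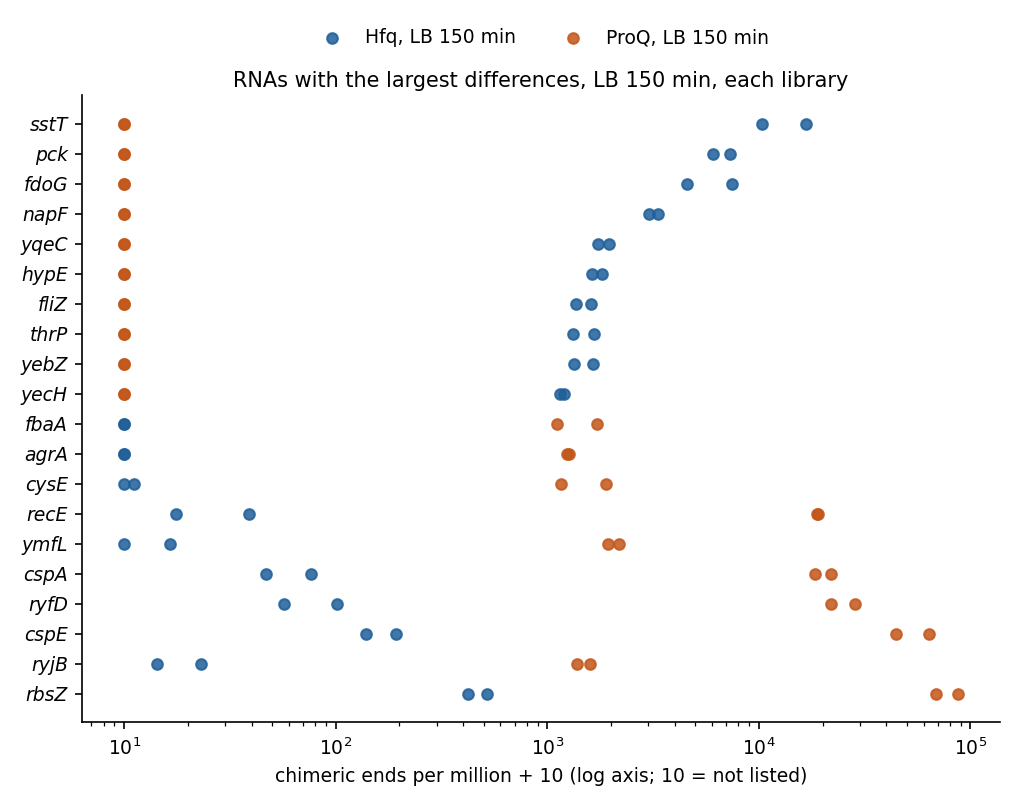
RNAs with the largest differences between Hfq and ProQ after 150 min in LB, in CPM plus 10 on a log axis, with 1 point per library. The sRNA rbsZ averages 78083 on ProQ and 459 on Hfq.

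Of 29 Hfq-dependent sRNAs after 150 min, 17 were measured higher on Hfq and 3 on ProQ, and 8 did not pass (17 and 3 adjusted over the list alone; camera adjusted p = 0.272). Examples are arcZ (77796 CPM on Hfq and 4088 on ProQ; 4.26, SE 0.18), gcvB, which represses amino acid transport genes (65722 and 20723; 1.67, SE 0.12), and mgrR (4.77, SE 0.51). On the ProQ side, mcaS had 13132 on Hfq and 62559 on ProQ (-2.25, SE 0.09). Among the 8 that did not pass was chiX (3.29, SE 2.74). Its SE takes in the Hfq libraries without proQ, which share the fit and where the replicates of chiX differed widely. The hfq mRNA was higher on Hfq (4.50, SE 0.34). Of 9 RNAs tied to ProQ, 6 were higher on ProQ (6 adjusted over the list alone), with camera adjusted p = 4.50e-04 and adjusted p = 0.0957 with an estimated correlation. Of 8 toxin-antitoxin RNAs, 6 were higher on ProQ (6 adjusted over the list alone; camera adjusted p = 1.24e-04, and adjusted p = 0.0957 with an estimated correlation), among them ibsA, at 721 ± 280 CPM on ProQ and not listed on Hfq. Among 22 global regulators, 7 were higher on Hfq and 8 on ProQ (7 and 8 adjusted over the list alone; camera adjusted p = 0.414). The nucleoid protein genes hupB (3439 ± 299 on Hfq, 20494 ± 1877 on ProQ; -2.57, SE 0.23) and hns (-3.17, SE 0.35) were on the ProQ side. The median of that list was 1.19 and its mean -0.27, so the members went both ways. Among 15 iron and respiration genes 5 were higher on Hfq, such as iscR, and 4 on ProQ, such as sodB (385 ± 63.2 on Hfq and 5186 ± 86.5 on ProQ; -3.77, SE 0.22; 5 and 4 adjusted over the list alone; camera adjusted p = 0.355). The tRNA list had 1 of 21 measured higher on Hfq and 2 on ProQ (1 and 2 adjusted over the list alone), with camera adjusted p = 4.50e-04 and adjusted p = 0.437 with an estimated correlation. Plain limma calls numbered 860, 604 higher on Hfq and 256 on ProQ; median-of-ratios size factors moved the median of all genes from 1.07 to 1.60.

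The 2 LB comparisons named partly the same genes. Among 1182 genes tested in both, 276 were measured higher on Hfq in both, of 442 at OD 1 and 410 at 150 min, where independent lists would share 153. On the ProQ side 70 were shared, of 126 and 100, against 10.7 for independent lists. Another 6 genes, aspX, csrB, exuT, kbl, ybiA and ydgA, went opposite ways; they were named after their values were seen. Between LB and M63 at OD 1, 124 genes were shared on the Hfq side and 31 on the ProQ side, against 58.6 and 3.60 for independent lists. Another 14 went opposite ways: acpP, aspX, cheA, cspD, fliA, frdA, insH1, lptM, nmpC, proP, rdcA, spf, sucC and talB were all measured higher on ProQ in LB and on Hfq in M63. Of these only spf (-0.87 and 4.26, the first with the opposite sign under median-of-ratios size factors) was listed on ProQ in M63, and the others rest on a level of 0 there. These too were named after their values were seen. Those 2 comparisons come from 1 fit and share its spread estimate, which can account for part of that excess. In addition, the numbers for independent lists take in genes with too few counts for a measured call. Only 665 of 1468 genes in LB at OD 1, 261 of 1468 in M63 and 693 of 1568 at 150 min met the count criteria. The same genes being abundant in both conditions can therefore account for much of each excess, so the overlaps are no evidence of a shared preference.

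Many pairs seen on ProQ were also listed on Hfq. Of 377 pairs listed in both ProQ libraries in LB at OD 1, 177 were listed in at least 1 Hfq library of that condition (46.95%, Wilson interval 42.0 to 52.0%). In M63 36 of 93 were (38.7%, Wilson interval 29.45 to 48.9%), and at 150 min 172 of 362 (47.5%, Wilson interval 42.4 to 52.7%). With partners drawn at random in proportion to their number of pairs, 7.60%, 2.90% and 8.78% would be expected. Asking for both Hfq libraries lowered the shares to 39.8% in LB at OD 1 and 40.3% at 150 min.

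Among pairs after 150 min, the largest differences were between pairs listed on a single chaperone. On Hfq these were chiX-chiZ (49961 ± 8092 CPM, SE of the log2 difference 3.62), arcZ-ypfM (27326 ± 2711), gcvB-sstT (26427 ± 9035), micA-pck (13068 ± 1666) and fdoG-sdhX (11663 ± 4002). On ProQ these were cspE-malM (69292 ± 22246), cspA-raiZ (39557 ± 4859), raiZ-ryfD (37653 ± 8779), mcaS-pflB (12583 ± 404) and recE with an intergenic window (8491 ± 556). The SE of chiX-chiZ takes in the Hfq libraries without proQ, which share the fit and had 20862 and 0 fragments of this pair. The Hfq libraries compared here had 16889 and 25876. The pair rbsZ-rybB reached 146940.3 ± 28366 CPM on ProQ and 450.4 ± 55.7 on Hfq (-8.34, SE 0.38). In all, 991 of 2922 pairs had a measured difference, 806 higher on Hfq and 185 on ProQ. Plain limma calls numbered 2014, 1375 and 639.

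**Figure D4:**
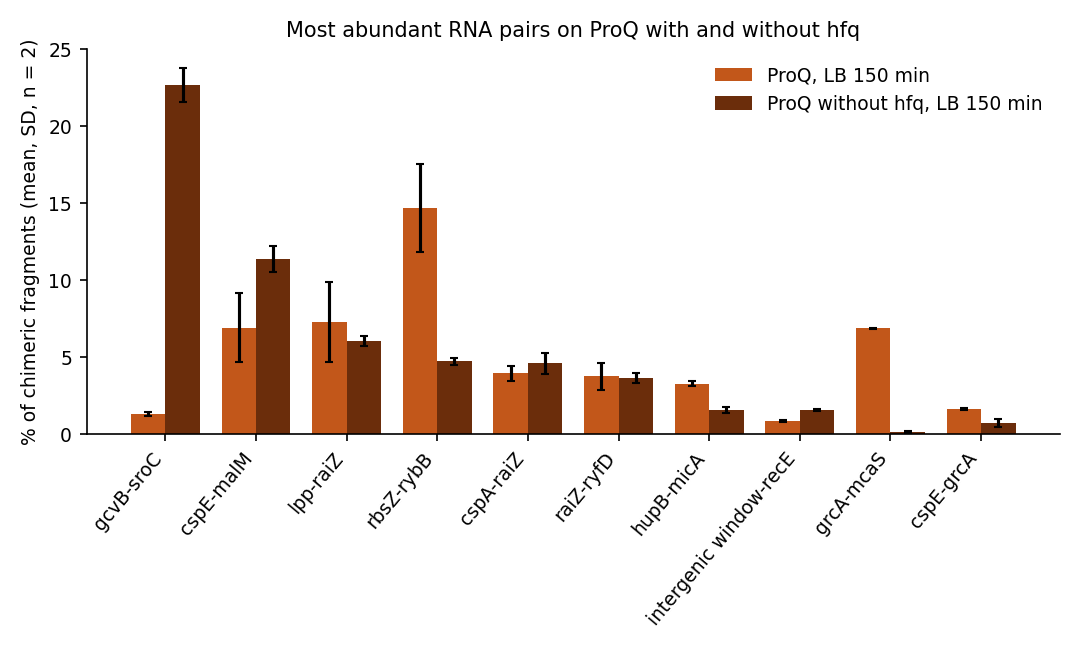
Abundant RNA pairs on ProQ with and without hfq after 150 min in LB, in percent of fragments, with bars at the mean and SD of 2 libraries. The pair rbsZ-rybB averages 14.7% with hfq and 4.74% without it.

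Of the 57 known sRNA-target pairs fixed in advance, the number listed in both libraries of a group was 32 on Hfq and 19 on ProQ in LB, 34 and 4 in M63, and 30 and 16 after 150 min; it was 29 on Hfq without proQ and 7 on ProQ without hfq. The pair micF-ompF had 6588.5 ± 1347 CPM on Hfq and 248 ± 112 on ProQ after 150 min (4.72, SE 0.55), and eptB-mgrR 33134 ± 6167 and 675 ± 103 (5.59, SE 0.34). The pair ptsG-sgrS, of the glucose transporter mRNA and the sRNA that responds to sugar phosphate stress, was higher on ProQ, at 988 ± 273 against 431 ± 147 (-1.22, SE 0.43), and so was csgD-omrB (-4.38, SE 0.32). On ProQ ptsG-sgrS had 34 and 49 fragments. Median-of-ratios size factors moved the median of all pairs from 1.01 to 1.97, a shift toward Hfq. The ptsG-sgrS difference is not much larger than that shift, so it depends on the scaling. The pair hupA-raiZ had 772 ± 66.9 on ProQ and was not listed on Hfq.

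Between M63 and LB, hisG and tnaA were among the genes that differed most on Hfq. In M63 hisG, for the first step of histidine synthesis, had 38789 ± 1747 CPM, and it was not listed in LB. The tryptophanase gene tnaA had 9209 ± 134 in LB and was not listed in M63, and its leader gene tnaC had 19287 ± 1054 in LB and 12.0 in M63 (-12.15, SE 1.54). The sRNA spf was higher in M63 (4.13, SE 0.22), and so were ryhB (12936 against 410.0 CPM; 4.96, SE 0.36), sdsR (5477 against 92.8; 5.99, SE 0.71) and grcA (25933 ± 675 against 700.3 ± 233; 5.29, SE 0.41). Also higher were queE (9.61, SE 1.75), yejA (8.38, SE 0.98), adhE (7.87, SE 1.32), lysC (5.53, SE 0.47), hybO (5.49, SE 0.89) and gltB (5.24, SE 0.60), and fruK was listed in M63 only, at 2079.5 CPM. Lower in M63 were gcvB (7748 against 82633; -3.44, SE 0.84), omrA (-7.27, SE 1.18), micF (-4.25, SE 0.37), argT (119 against 16736; -7.12, SE 0.87), tdcA (-10.36, SE 1.08) and thrP (-5.88, SE 0.42). The genes fabD, tnaB, narK, cyoB and ivbL were listed in LB and not in M63. A measured difference was seen for 784 of 1468 genes, 398 higher in M63 and 386 in LB.

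Of 34 amino acid biosynthesis genes on Hfq, 24 were measured higher in M63 and 3 in LB (25 and 4 adjusted over the list alone). Examples are thrA (1469 ± 501 CPM in M63 and 124 ± 20.2 in LB; 3.54, SE 0.46), metE, listed in M63 only at 549 ± 226, and, going the other way, ilvB, listed in LB only at 855 ± 35.5. Camera gave adjusted p = 4.01e-04, and adjusted p = 0.814 with an estimated correlation. Of 19 transport genes of the GcvB type 5 were higher and 9 lower (5 and 10 adjusted over the list alone; camera adjusted p = 0.678), with brnQ (4.59, SE 0.89) higher and dppA (-4.19, SE 0.30) lower. Of 37 ribosomal protein genes 22 were lower and 3 higher in M63 (22 and 3 adjusted over the list alone), as rplK (-1.59, SE 0.28) and rpsT (-4.11, SE 0.46) were lower; camera gave adjusted p = 4.01e-04, and adjusted p = 0.814 with an estimated correlation. Of 29 Hfq-dependent sRNAs 9 were higher and 8 lower (9 and 8 adjusted over the list alone; camera adjusted p = 0.739), with rprA (2.14, SE 0.28) and fnrS (1.90, SE 0.26) higher, and omrB (-2.45, SE 0.41), cyaR (-1.06, SE 0.22) and glmZ (-1.16, SE 0.24) lower. Among 25 sugar uptake genes 7 were higher, such as ptsG (9854 ± 1779 against 1725 ± 53.1; 2.49, SE 0.27), and 11 lower, such as treB, not listed in M63 (7 and 11 adjusted over the list alone; camera adjusted p = 0.678). Without the first Hfq library in LB the measured count was 477, and with median-of-ratios size factors it was 782, split into 257 higher and 525 lower, since that scaling moved the median log2 difference of all genes from 0.161 to -1.004. The signs of dsrA and micA changed with it.

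On ProQ, raiZ remained abundant in both media while GcvB and several mRNAs were lower in M63. The sRNA gcvB had 2242 ± 3171 CPM in M63 and 37205 ± 293 in LB (-6.97, SE 1.45), cyaR was lower (-2.29, SE 0.36), and so were sroC (-5.60, SE 1.37) and raiA (-3.08, SE 0.54). Not listed in M63 were yacL (4457 in LB), ivbL (3975), the asparaginase gene ansB (3951), cstA (3418), tnaB (3120.3), dppA (2978 ± 101), cspD (2514 ± 556), the nucleoid protein gene hupA (1016 ± 77.1) and hfq (539.0 ± 8.80). Higher in M63 were the fructose transporter gene fruA (27921 ± 751, not listed in LB), bssR (3454, not listed in LB), gltB (2206 ± 1064, not listed in LB) and glpC (2029, not listed in LB). So were aroG (15055 ± 11447 against 364 ± 514; 8.53, SE 1.80), osmB (3274 against 29.0; 7.46, SE 0.81), ydiH (6.85, SE 1.11), rprA (3802 against 79.4; 5.56, SE 0.53), cspA (1.81, SE 0.33) and ptsG (3.04, SE 0.47). A measured difference was found for 130 genes, 29 higher in M63 and 101 in LB.

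Camera called 5 lists lower in M63 on ProQ. These were Hfq-dependent sRNAs (adjusted p = 0.0036), RNAs tied to ProQ (0.0023), toxin-antitoxin RNAs (0.0489), transport genes of the GcvB type (0.0036) and flagella and chemotaxis (0.044). With an estimated correlation none passed: adjusted p = 0.317, adjusted p = 0.305, and adjusted p = 0.323 for each of the other lists. The measured members were 2 higher and 4 lower of 29 Hfq-dependent sRNAs (1 and 4 adjusted over the list alone), 1 and 4 of 10 RNAs tied to ProQ (0 and 4 adjusted over the list alone), 2 and 1 of 10 toxin-antitoxin RNAs (0 and 1 adjusted over the list alone), 0 and 3 of 19 transport genes of the GcvB type (0 and 3 adjusted over the list alone), and 0 and 5 of 20 flagellar genes (0 and 4 adjusted over the list alone). Among these, sibD (1.52, SE 0.54) and agrA (2.10, SE 0.82) were higher and sibE (-3.12, SE 0.53) lower, with fliA listed in LB only, at 1134.5 ± 33.6. The medians were above 0 for 4 of these lists, at 0.31 for the Hfq-dependent sRNAs, 0.27 for the toxin-antitoxin RNAs, 0.31 for the transport genes and 0.52 for the flagellar genes, and -0.04 for the RNAs tied to ProQ; the test sets them below the median of all genes. Plain limma calls numbered 1095, 939 higher and 156 lower, against 209 with limma-trend and 140 with only the groups compared (median of all genes 2.75, and 2.25 with median-of-ratios size factors); the M63 libraries of ProQ hold 6190 and 4391 fragments, which sets genes without an end to a higher fitted level there.

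For 11 of the 38 genes with at least 10 ends in each of the 8 libraries, the Hfq-over-ProQ ratio differed between media in limma. It was higher in M63 for spf (log2 difference of ratios 5.13, SE 0.47), grcA (3.90, SE 0.66), rybB (3.08, SE 0.72), the cold shock genes cspB (2.85, SE 0.64) and cspG (2.25, SE 0.69), sodB (2.43, SE 0.77), fnrS (1.58, SE 0.49) and cyaR (1.23, SE 0.43). It was lower for omrB (-2.84, SE 0.66), sdhX (-2.58, SE 0.58) and glmZ (-2.17, SE 0.54). With median-of-ratios size factors 14 genes passed, 4 higher and 10 lower, and 7 of them were among the 11; that scaling moved the median over all genes from -1.61 to -2.28. Plain limma calls numbered 803, 219 higher and 584 lower, and with limma-trend 506 were higher and 289 lower. As 883 of 1468 genes had an unadjusted p under 0.05, the adjustment behind the 11 genes was slight.

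Without proQ, flagellar RNAs were almost gone from Hfq chimeras. The flagellin mRNA fliC fell from 19562 ± 291 CPM with proQ to 22.4 ± 0.40 without it (-9.75, SE 0.39), and fliX, an sRNA from its 3' end, from 14870 to 68.6 (-7.69, SE 0.75). The flagellar-regulated gene flxA had 3605 ± 258 with proQ and motR 1686, and neither was listed without it. The master regulator gene flhD had 1156 ± 102 and 94.8 ± 4.60 (-3.60, SE 0.56), and fliZ was lower too (-5.19, SE 0.23). All 20 tested genes of flagella and chemotaxis fell, 19 of them measured (19 adjusted over the list alone), with camera adjusted p = 5.45e-20, and adjusted p = 0.0062 with an estimated correlation. Other RNAs that fell were modA (-8.67, SE 1.37), the sRNA uhpU (-3.45, SE 0.33), treC (-2.82, SE 0.46) and the porin mRNA ompF (-1.68, SE 0.26). Each genotype is a single strain.

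**Figure D5:**
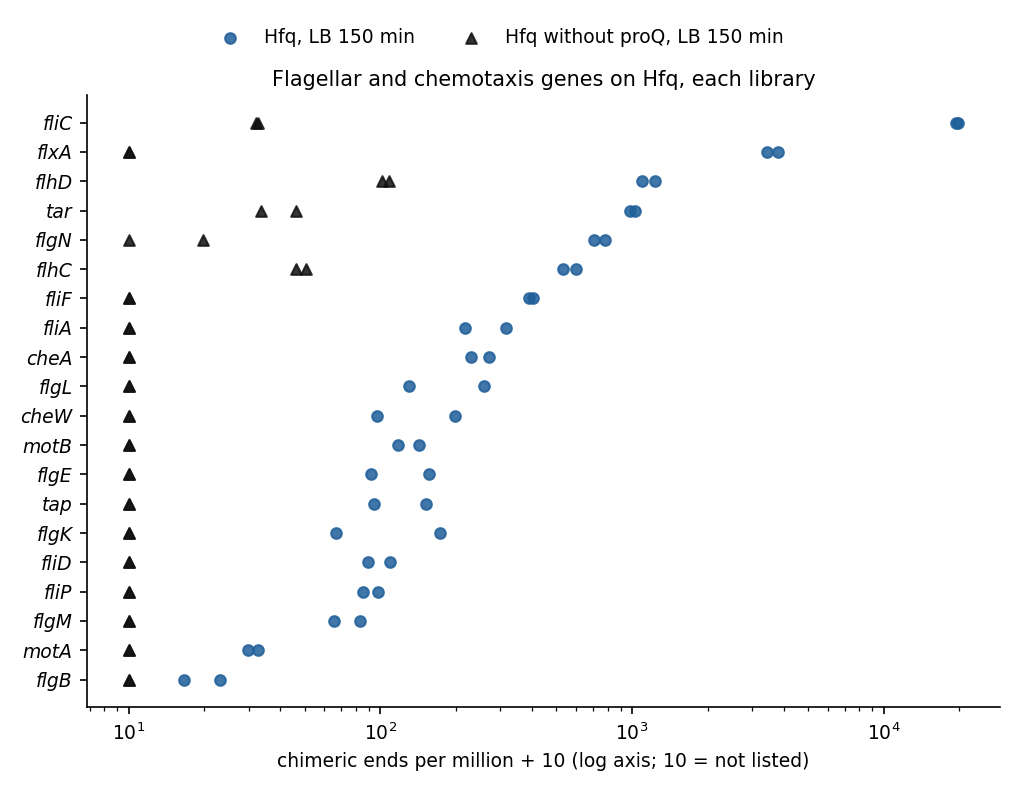
Flagellar and chemotaxis genes in Hfq libraries with and without proQ, in CPM plus 10 on a log axis, 1 point per library. The mRNA fliC averages 19562 with proQ and 22.4 without it.

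The envelope-stress sRNAs OmrA, OmrB and CpxQ were higher on Hfq without proQ. The sRNA omrA had 3038 CPM against 404 (2.88, SE 0.29), omrB 4233 against 884.0 (2.21, SE 0.31) and cpxQ 18922 against 6176 (1.65, SE 0.28); omrA and omrB share sequence, so their split is uncertain. Also higher were ydcH (1.57, SE 0.19), the glycerol kinase gene glpK (1.44, SE 0.36), tdcE (1.35, SE 0.32), ryhB (11143 against 4503; 1.31, SE 0.27), yacL (1.23, SE 0.23), ompC (4586 ± 459 against 2192 ± 38.4; 1.07, SE 0.14) and dmsA (0.98, SE 0.25), the last with the opposite sign when no flank was counted. Of 29 Hfq-dependent sRNAs 7 rose, 2 fell and 20 did not pass (7 and 3 adjusted over the list alone; camera adjusted p = 0.916): sdsR (2.70, SE 0.40), oxyS (0.87, SE 0.14) and arcZ (108860.2 against 77796; 0.48, SE 0.06) rose, and gcvB fell by 0.30 on the log2 scale (SE 0.06). Among 17 outer membrane protein genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.918), and among 22 amino acid biosynthesis genes 5 rose, such as cysJ (2.63, SE 0.57), and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.693). Of 1568 genes 317 had a measured difference, 201 higher without proQ and 116 lower. With only the groups compared the count was 202. With the second library of the proQ deletion left out, which leaves a single library in that group, most of the 317 calls did not recur. Median-of-ratios size factors moved the median of all genes from 0.34 to 0.54.

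Among pairs without proQ, the largest rises were omrA-tdcA (2128.5 ± 657 against 275.5 ± 116; 2.98, SE 0.48), omrB-tdcA (2.55, SE 0.46), cpxQ-uspA (2.51, SE 0.62), cpxQ-dtpB (2.23, SE 0.44) and cpxQ-glpK (2.12, SE 0.52). The pairs chiX-tdcA (15054 ± 1271 with proQ), fliC-mgrR (10969 ± 1605), fliC-fliX (9652 ± 1364), fliC-tdcG (4608 ± 111) and flxA-fnrS (4506 ± 414) were not listed without proQ. The sRNA chiX had 28967 ends in replicate 1 without proQ and 0 in replicate 2, so the absence of chiX-tdcA rests on replicate 1 alone. The known pair arcZ-flhD fell from 314 ± 73.5 to 10.3 ± 14.5 (-5.39, SE 1.19). Of 2922 pairs, 847 had a measured difference, 535 higher and 312 lower without proQ. With the second library of the deletion left out, which leaves a single library in that group, most of these calls did not recur.

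Without hfq, ProQ chimeras were dominated by GcvB with its sponge SroC, while several sRNAs were lower. The sRNA gcvB had 135857 ± 7195 CPM against 20723 ± 789 with hfq (2.72, SE 0.14), and sroC 116029 ± 5575 against 6675 ± 528 (4.12, SE 0.87). The mRNA cspE rose less (90672 ± 120.3 against 54004 ± 13587; 0.77, SE 0.20). By contrast, mcaS fell from 62559 to 1224 (-5.69, SE 0.31), rybB from 76469 to 27757 (-1.45, SE 0.27) and rbsZ from 78083 to 28411 (-1.46, SE 0.24). Lower too were cpxQ (-3.83, SE 1.00), arcZ (814 against 4088; -2.35, SE 0.35), fnrS (-2.07, SE 0.51) and flxA (-6.17, SE 1.24), and nrfD (3726 with hfq), omrB (2564), uhpU (1561), cheA (1359 ± 37.9) and glnZ (1138) were not listed without hfq. The chitooligosaccharide genes chiQ (9138 ± 500) and chiP (2554 ± 434), silenced by ChiX, were listed without hfq and not with it. Of 1568 genes 141 had a measured difference, 41 higher without hfq and 100 lower. With the second library of the deletion left out, which leaves a single library in that group, most of these calls did not recur.

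Of 29 Hfq-dependent sRNAs on ProQ, 2 rose and 9 fell without hfq (2 and 9 adjusted over the list alone), with camera adjusted p = 1.29e-07 and adjusted p = 0.0374 with an estimated correlation. On log2 of CPM plus 10, over the genes with enough ends in the compared groups, the list had adjusted p = 0.245. Among 21 tRNA genes 11 rose and 1 fell (11 and 1 adjusted over the list alone), with camera adjusted p = 0.0019 and adjusted p = 0.301 with an estimated correlation. The tRNA genes leuT (7598 ± 1354 against 29.7 ± 42.0; 8.59, SE 0.88), glnX (6238 ± 0.60, not listed with hfq), glnW and proM rose, although near-identical copies make the single genes uncertain. Of 20 flagellar genes 1 rose and 4 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.0041, and adjusted p = 0.147 with an estimated correlation). The class II sRNAs (1 of 5 fell, 1 adjusted over the list alone) and the toxin-antitoxin RNAs (1 of 8 rose and 2 fell, 1 and 2 adjusted over the list alone) had camera adjusted p = 0.0177 and 0.014, and adjusted p = 0.165 for both with an estimated correlation. Plain limma calls numbered 634, 496 higher and 138 lower, against 118 with no filter, 207 with limma-trend and 128 with only the groups compared, and the median of all genes was 1.36, or 1.09 with median-of-ratios size factors.

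The pair gcvB-sroC rose from 13007 ± 1202 to 227074.5 ± 11088 CPM on ProQ without hfq (4.13, SE 0.75; limma adjusted p = 0.0023), where it made up 22.7% ± 1.11 of all fragments. In this comparison 2417 of 2922 pairs had an unadjusted p under 0.05 and 2388 passed after adjustment, so the adjustment was slight. Other pairs listed without hfq and not with it were chiQ-yffL (12814 ± 2196), glnX-leuT (9453 ± 454), cyaR-garD (7354 ± 1289), glpA-rbsZ (6574 ± 1928) and chiP-malM (4065 ± 282). The pairs cyaR-glpB (9484 ± 904 with hfq), flxA-fnrS (8680 ± 1562), yffL with an intergenic window (8246 ± 176), cyaR-nrfD (7265 ± 223) and frdA-mcaS (4532 ± 987) were not listed without it. The pair rbsZ-rybB fell from 146940.3 ± 28366 to 47355 ± 2238 (-1.62, SE 0.39). Of 2922 pairs 211 had a measured difference, 59 higher and 152 lower without hfq. Of the 172 ProQ pairs also listed on Hfq, 76 were listed on ProQ in the absence of hfq (44.2%), and of the 190 pairs not listed on Hfq also 76 (40.0%). Thinning the listed fragments of the ProQ libraries to the depth without hfq kept 99.2% and 99.6% of these pairs, but this does not redo the call that decides whether a pair is listed, so it leaves open how much of the loss is due to depth.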

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

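In these paragraphs the test of a few dominant RNAs and limma's test of the difference between media were set before their results were seen; the minimum of 10 ends behind the 11 genes below and the tests of exchanged labels, spill-over, depth, the master regulator, composition and copies were chosen only after. For 11 genes the Hfq-over-ProQ log2 ratio differed between M63 and LB in limma's test of that difference, among 38 genes with at least 10 ends in each library. It was higher in M63 for spf (5.13, adjusted p = 1.42e-04), grcA (3.90), rybB (3.08), cspB (2.85), sodB (2.43), cspG (2.25), fnrS (1.58) and cyaR (1.23), and lower for omrB (-2.84), sdhX (-2.58) and glmZ (-2.17). With median-of-ratios size factors 7 of the 11 still passed. Camera also set 2 gene lists apart: ribosomal proteins (lower in M63, adjusted p = 0.0016, and adjusted p = 0.951 with an estimated correlation) and amino acid biosynthesis (higher, adjusted p = 0.012, and adjusted p = 0.743 with an estimated correlation). Neither list has a member with enough ends in all 8 libraries, so both rest on genes near 0 on ProQ.

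The first pattern is in the untagged controls. The untagged library of replicate 2 labelled LB (899 fragments) had similarities of 0.661 and 0.662 to the Hfq libraries in M63 and 0.398 and 0.399 to those in LB, and the one labelled M63 (873 fragments) 0.702 and 0.718 to Hfq in LB against 0.369 and 0.378 in M63. This may mean that the medium labels of the 2 untagged libraries are exchanged. A first test, by pairs found in a single medium, gave a mixed answer (19.35% against 2.22% for the library labelled LB, and 4.35% against 4.70% for the one labelled M63), and similarity was chosen after that. Spill-over of Hfq reads is argued against for the LB library, where 36.63% of fragments recur by coordinates in the deeper Hfq library, against 62.34% for the other Hfq replicate (binomial SD 1.63). For the M63 library 75.12% recur, against 76.61% for the other replicate and 77.64% for the library itself (SD 1.47), so spill-over cannot be told apart there from real fragments.

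The second pattern is the fall of flagellar RNAs on Hfq without proQ. Shallower libraries are argued against, as the smaller library without proQ holds 623592 fragments and the larger one with proQ 464706. A few dominant RNAs are argued against too, since the 5 most abundant held 33.57% ± 2.38 of ends with proQ and 35.44% ± 0.52 without it. All 20 tested flagellar genes fell when the 5 most abundant RNAs were left out. With shares so alike, that test could hardly have come out otherwise. Another change in the strain that lowers the flagellar master regulator stays open: flhD fell by 3.60 on the log2 scale, flhC fell by 3.84, and each genotype is a single strain. An effect of ProQ on flagellar gene expression is therefore a hypothesis that these libraries cannot tell apart from such a change.

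The third pattern is the rise of gcvB-sroC on ProQ without hfq, picked after the data were seen in place of a pattern on shared pairs whose tests did not decide. A loss of other pairs is argued against as the whole cause: over the median of 67 pairs the rise was at least 3.76 on the log2 scale in each of 4 library pairings, against 2.93 at the upper end of the central 95% of the other pairs, with gcvB-gltI higher still at 5.13. As the pair was picked after its values were seen, its place above the other pairs is no independent support. A loss of other pairs alone would raise those that remain alike, and the rise over their median exceeds that. Copies of few fragments are argued against, since distinct fragments numbered 1701 and 1976 without hfq and 359 and 409 with it. Spill-over from Hfq libraries is argued against as well, because it would bring at least 71193 fragments of the 20 most abundant Hfq pairs. These ProQ libraries hold 15244 and 17849 fragments in all. The 123 and 141 fragments of these pairs could therefore not have reached that number, and the library sizes alone decide. With hfq present the pair was already listed on ProQ, at 13007 ± 1202 CPM after 150 min. On Hfq it had 9478 ± 8985 there (1193 and 7357 fragments), so those replicates differed widely. In LB at OD 1 it had 955 and 496 fragments on ProQ and was not listed on Hfq. A candidate explanation is that more GcvB and SroC pass to ProQ when Hfq is absent. Their levels in the total RNA libraries of that deletion, not analysed here, would test whether more of either RNA is present instead, so this stays open.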

How the results depend on the processing

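The alternatives were chosen in advance, apart from those on measured calls, crossed replicate numbers, log2 of CPM plus 10, and identical fragments and replicates in the tagged-untagged contrast. Of 155 recomputed counts of plain calls 123 stayed within 1.5 times the reported count and 32 moved further, and of 151 counts of measured calls 138 and 13. A count within that range can still hide a changed split. For Hfq against ProQ in M63, limma-trend gave 899 plain calls, 847 higher on Hfq and 52 on ProQ. It shared 348 with the 672 reported, of which 291 were higher on Hfq. For the difference between media it gave 506 higher and 289 lower, against 219 and 584. Of 208 list tests 184 kept their direction and side of the threshold, 23 lost significance and 1 gained it. Of 7958 values of single genes or pairs 7244 kept both, 509 lost significance, 185 gained it and 20 changed sign. Among the features with the largest changes, 2152 of 2257 values kept both, 104 lost significance and 1 changed sign.

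A filter of 50 counts tests fewer genes and gave fewer calls by construction: 595 for Hfq against ProQ in LB at OD 1, 472 at 150 min, 478 for the medium on Hfq (476 measured), 561 for the medium on ProQ, 428 for the difference between media, 168 without proQ (168 measured) and 61 without hfq (57 measured). For pairs it gave 889 for Hfq against ProQ, 325 without proQ (301 measured) and 846 without hfq (109 measured). Fitting only the groups compared leaves fewer libraries for the spread: it gave 396 for M63, 140 for the medium on ProQ, 202 without proQ (202 measured), 128 without hfq, and for pairs 485 without proQ (485 measured) and 208 without hfq. Limma-trend gave 209 for the medium on ProQ, 207 genes and 226 pairs without hfq. No filter gave 118 genes and 197 pairs without hfq, and no flank 130 measured calls in M63; the cause was not tested. Asking for a pair in both Hfq libraries, a stricter criterion, lowered the shared ProQ pairs to 39.79% in LB at OD 1 and 40.33% at 150 min.

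With median-of-ratios size factors micA (1.34), omrB (1.36), spf (0.51) and raiA (0.25) changed sign for Hfq against ProQ in LB at OD 1, and chiX (-1.05), dsrA (-0.41), micA (-0.32) and arcZ (-1.0025) for the medium on Hfq, since that scaling shifts all genes alike. Limma-trend changed the sign of proQ (0.38), rydC (0.57) and sibA (0.0528) in the difference between media (proQ and rydC are not listed in any ProQ library there, so their fitted values depend on the prior count), and no flank that of dmsA without proQ (-0.27); the cause was not tested.

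Leaving out 1 library at a time, the lone library left was assumed to vary like the other groups. The counts below are of calls in each reduced fit, and part of them were not among the reported calls. Calls for the medium on Hfq ran from 481 (without Hfq LB replicate 1) to 590 (measured 477 to 588), and for the difference between media from 362 (without Hfq LB replicate 2; 477 without replicate 1) to 886. Without proQ they ran from 146 (without deletion replicate 2; 207 without replicate 1) to 339 (measured 146 to 333), and without hfq from 111 (without deletion replicate 2) to 182 (measured 84 to 150). Pairs without proQ ran from 550 (without deletion replicate 2; 588 without replicate 1) to 1155 (measured 550 to 1087). The Hfq-ProQ differences ran from 353283 to 481294 fragments, 2105.3 to 2323.3 pairs, 5.48 to 5.89 points of sRNA ends, 21.8 to 21.83 points of second positions and 23.87 to 26.2 points of pairs with an sRNA, each with exact p = 0.25, the smallest that 1 library per group allows. The tagged-untagged difference ran from 199778 to 271734 fragments. Shares of ProQ pairs also on Hfq, from a single ProQ library, ran from 38.73% to 39.82% in LB at OD 1 and from 33.52% to 34.27% at 150 min.

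Signs that turned on 1 library belonged to features not past the threshold with all libraries. The log2 difference ran from -1.52 to 0.38 for sroC in Hfq against ProQ at 150 min, from -1.98 to 2.35 for oxyS and -2.34 to 1.84 for sibA in the medium on ProQ, and from -1.96 to 2.37 for oxyS in the difference between media. Without proQ it ran from -1.41 to 0.49 for sroC and -0.18 to 0.16 for micA, and for pairs from -3.18 to 2.26 for gcvB-livJ (Hfq against ProQ) and -2.53 to 1.33 for cycA-gcvB (without hfq); the first is not listed on ProQ and the second not without hfq, so these are fitted values and no folds.

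The groups share only replicate numbers. A replicate block gave 941 calls in LB at OD 1, 672 in M63, 821 at 150 min, 735 for the medium on Hfq, 1112 on ProQ, 796 for the difference between media, 270 without proQ, 568 without hfq, and for pairs 2042, 969 and 2474 in the order of the report, all within 1.5 times the reported counts. Correlations of same-number deviations ran from -0.209 to 0.224 with mixed signs, over 38 genes in experiment 1 and 74 in experiment 2. With the numbers crossed in 1 group, calls numbered 653 in M63, 728 for the medium on Hfq, 1071 on ProQ and 489 without hfq. The ProQ libraries are shallower and their replicates less alike: the Pearson r of log2 levels was 0.355 for ProQ in M63 and 0.449 without hfq, against 0.937 for Hfq in LB at OD 1, and whether depth accounts for this was not tested.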

Other observations

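Without hfq the ProQ libraries also held fewer pairs with an sRNA and more tRNA ends. Pairs with an sRNA made up 39.3% ± 1.39 of distinct pairs there, against 56.35% ± 0.10 with hfq, and sRNA ends sat in the second position in 58.1% ± 0.74 against 64.1% ± 0.18. Ends in the 100 nt after coding genes made up 17.9% ± 0.33 without hfq and 13.8% ± 2.56 with it, and ends in tRNA genes 2.94% ± 0.98 and 0.15% ± 0.07. Each is a mean ± SD of 2 libraries and was not tested. Where both partners are sRNAs, an sRNA end always sits in the first position. Of such pairs, gcvB-sroC made up 22.71% of fragments without hfq and 1.30% with it, and rbsZ-rybB 4.74% and 14.69%.

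Several sRNAs had more partners on Hfq than on ProQ in LB at OD 1, in libraries that are also deeper: cyaR met 472.5 and 90.0 RNAs on average, arcZ 321.5 and 8.0, and gcvB 152.5 and 42.0. The cold shock mRNA cspE went the other way, with 2.5 partners on Hfq and 44.0 on ProQ, and so did raiZ, with 9.5 and 40.5. The sRNA rbsZ had 7.0 and 7.5.

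Some abundant pairs were listed in 1 replicate and not in the other. The pair chiX-chiZ had 20862 fragments in replicate 1 of Hfq without proQ and 0 in replicate 2. The pair chiX-gatZ had 4500 and 0 in the same libraries, and chiX-proQ 0 and 879 in the Hfq libraries with proQ at 150 min. A value of 0 for a pair in these files can therefore stand beside many fragments in the other replicate.

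The 6 genes measured higher on one chaperone at OD 1 in LB and on the other at 150 min were named after their values were seen. The Hfq-over-ProQ log2 difference was -1.49 and 2.45 for aspX, and -3.66 and 4.01 for exuT. The sRNA csrB was not listed on ProQ at OD 1 (1345 CPM there at 150 min), and kbl, ybiA and ydgA were not listed on ProQ at 150 min (266, 315 and 219.6 CPM there at OD 1). The difference between the experiments was not tested.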
